A study of Homo sapiens with 9 samples.

How the data were processed

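Messenger RNA of 9 Hap1 libraries was measured, 3 for each of the SARS2 genotypes WT, R227Q and H448L, all after 6 days without doxycycline. Per the labels' protocols, cell lysates went to a commercial sequencing service that extracted RNA, captured poly-A mRNA, made second-strand cDNA with tagmentation and amplified Illumina libraries. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here, nor whether counting used strand.

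The authors deposited estimated counts per gene, per the file headers, without normalization, in 1 table per submission to the service. The same tables hold CPM, per the file headers: each CPM equals the deposited count divided by the library's total and scaled to 1000000, which was checked and held within a tolerance of 1e-05. Between 89.1% and 90.1% of the count values per library, zeros included, were whole numbers with no tolerance, and 70.4% to 72.5% of the values above 0. The rest were fractions, and counts were rounded before testing. Fractions would arise if reads were shared between genes, which was not tested. Paralogs such as ribosomal proteins, histones, metallothioneins and IFITM genes, mitochondrial genes with nuclear copies, and overlapping genes are reported as uncertain for that reason. Each table had 78986 entries, of which 92 were ERCC spike-in controls that were left out of the tests and 78894 were genes. Of these, 36134 had no name and 2111 shared a name with another, so genes were kept by identifier. Gene positions came from GENCODE gene models on GRCh38. All columns were matched to a library by the names in the labels.

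Total counts ran from 9900892 to 12991050 per library, and 28041 to 29824 genes had a count. Mitochondrially encoded mRNAs took 4.38% to 5.94% of counts, mitochondrial rRNAs 0.757% to 1.2%, cytosolic ribosomal protein genes 13.4% to 14.6%, the 10 most abundant genes 6.81% to 7.92%, and protein-coding genes 93.3% to 93.9%. No library was a copy of another. Within a submission the counts of libraries of a group differed by 1.48 to 2.41 times sampling noise (chi-square per degree of freedom), and between submissions by 20.2 to 21.4 times.

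The groups, tests, submission term, filters, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Genes were kept by edgeR's filterByExpr with the groups (16908 genes), and factors were TMM (0.969 to 1.02). Models held the 3 groups and the submission, on all 9 libraries, with 5 residual degrees of freedom, and were tested with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The common biological coefficient of variation was 2.96% with the submission term and 12.7% without it. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. A standard error is the log2 fold change divided by the root of its F statistic. Within-submission values are differences of mean log2 CPM with a prior count of 2; SDKYMR holds no H448L library and 1 R227Q library, and 4LJFHN holds 1 WT library. These differences are printed without a test; 4LJFHN was also fitted alone as an alternative.

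Of the 22 lists tested, 1 is not reported here, and the others were mitochondrially encoded mRNAs, nuclear OXPHOS subunits, mitochondrial ribosomal proteins, mitochondrial and cytosolic aminoacyl-tRNA synthetases, the integrated stress response (ATF4 targets), serine synthesis and mitochondrial one-carbon enzymes, mitochondrial chaperones and proteases, ER chaperones, glycolysis and hypoxia targets, sterol biosynthesis, the tricarboxylic acid cycle and fatty acid oxidation, mitochondrial biogenesis regulators and nucleoid, interferon-stimulated genes, cell cycle and proliferation, cytosolic ribosomal proteins, replication-dependent histones, and markers of epithelial cells, fibroblasts, haematopoietic cells, and neuronal and embryonic kidney lines. SARS2 was kept out of the synthetase list. Each list was tested per comparison with camera at its preset correlation of 0.01 on log2 CPM, adjusted over the 22 lists, and again with an estimated correlation and with fry, whose test asks whether a list's genes move one way and compares them with no other genes. Over the 66 tests camera called 20, fry 24, and camera with an estimated correlation 4, which were the integrated stress response and sterol biosynthesis in both variants against WT.

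Named genes followed a rule: SARS2 first; per comparison the 8 largest rises and 8 largest falls among called genes with a name and a mean of at least 5 CPM; the 3 members of each list with the smallest p; and ATF4, DDIT3, ASNS, TRIB3, CHAC1, GDF15, FGF21, PHGDH, PSAT1, SHMT2, MTHFD2, HSPD1, LONP1, TFAM and MYC where measured. FGF21 did not pass the filter. Genes outside the rule are named as such.

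Alternatives were DESeq2, limma-voom, RLE and upper-quartile factors, every gene with a count, a mean of at least 10 counts, no submission term, 4LJFHN alone, a replicate block with and without the submission term, the compared groups alone, thinning to the smallest library, protein-coding genes alone, library sizes without mitochondrial and ribosomal protein genes, a prior count of 0.5, and each library left out in turn. Leaving out WT 3 or R227Q 1 leaves 1 group without a library in a submission. Without WT 3, H448L is compared with WT only through R227Q libraries. A loess correction for GC content and length (span 0.5) and fold changes against unshared WT libraries were added after the data were seen. Shared controls were simulated 50 times.

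The scripts were tested on simulated counts of the same size with 200 changed genes. At simulated folds of 1.25, 1.5 and 2, edgeR recovered 52.2%, 68.7% and 90.9% for R227Q against WT with 4 false calls, 35.8%, 59.7% and 81.8% for H448L against WT with 7, and 41.8%, 73.1% and 84.8% for H448L against R227Q with 5. A simulated fall of the sterol list was recovered in each comparison (camera adjusted p of at most 0.012 with an estimated correlation). Camera at its preset correlation gave 1 false list call in H448L against R227Q and 0 in the others. Simulated genes varied independently of each other, so these false calls do not show the rate in the real data. There the estimated correlation within a list was as high as 0.447, for mitochondrially encoded mRNAs.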

Results

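Messenger RNA was sequenced in Hap1 cells, a near-haploid human line derived from a chronic myeloid leukaemia line. SARS2 encodes mitochondrial seryl-tRNA synthetase, the enzyme that loads serine onto mitochondrial tRNAs. The endogenous SARS2 gene had been deleted in these cells, and an inducible FLAG-tagged copy was left off for 6 days by omitting doxycycline. By this design, the remaining source of the enzyme was a myc-tagged copy that was wild type (WT), R227Q or H448L. Shut-off of the inducible copy was not tested here. The 3 groups had 3 libraries each. The column names placed the libraries in 2 submissions to the sequencing service, SDKYMR with 3 libraries (WT 1, WT 2 and R227Q 1) and 4LJFHN with 6 (WT 3, R227Q 2, R227Q 3 and the H448L libraries). Total counts were 12991050, 12877428 and 11055106 for WT 1 to 3, and 12276413, 11262316 and 12349129 for R227Q 1 to 3. For H448L 1 to 3 they were 11229588, 10834951 and 9900892. Levels are given as CPM, the count divided by the library's total and scaled to 1000000, so 1 count stood for 0.0770 to 0.101 CPM.

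The submissions differed strongly. Of 16908 genes tested, 7409 differed between submissions (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and the first principal component, with 63.8% of the variance, separated them. Across genes, the correlation of log2 CPM was 0.989 to 0.994 between libraries of the same submission and 0.966 to 0.973 between libraries of different ones. Every comparison carried a submission term, which was planned from the column names. After removal of that term the first component held 35.4% of the variance and separated the WT libraries (−23.8 to −20.5) from both variants (8.47 to 13.3). The groups were kept in the fit that removed the term, so this separation is not independent of the group labels. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical.

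SARS2 (ENSG00000104835, GRCh38 chromosome 19, 38915266 to 38930896, minus strand) was detected in each of the 9 libraries. Its level was 7.70, 8.54 and 6.20 CPM in WT 1 to 3, 8.68, 8.35 and 7.09 CPM in R227Q 1 to 3, and 7.88, 8.68 and 7.93 CPM in H448L 1 to 3. The means were 7.48 ± 1.2, 8.04 and 8.16 CPM (± SD, n = 3 each). The log2 fold change against WT was 0.18 ± 0.12 (SE) for R227Q and 0.28 ± 0.15 for H448L, and neither passed the test (edgeR adjusted p = 0.38 and 0.29). Within submissions the R227Q difference was 0.08 in SDKYMR and 0.31 in 4LJFHN, and the H448L difference was 0.37 in 4LJFHN. The H448L level differed from that of R227Q by 0.10 ± 0.13 (edgeR adjusted p = 0.85). These values are uncertain. The annotated gene overlaps MRPS12 on the opposite strand by 349 bases and a longer gene on its own strand (AC011455.2) by 15493 bases. The tables also do not tell transcripts of the deleted gene, the inducible copy and the constitutive copy apart. The labels add int14 to the name of the constitutive copy without saying what it is. Whether that copy's transcripts were counted under SARS2 is not given in the sources used here, so these levels may miss it.

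**Figure D1:**
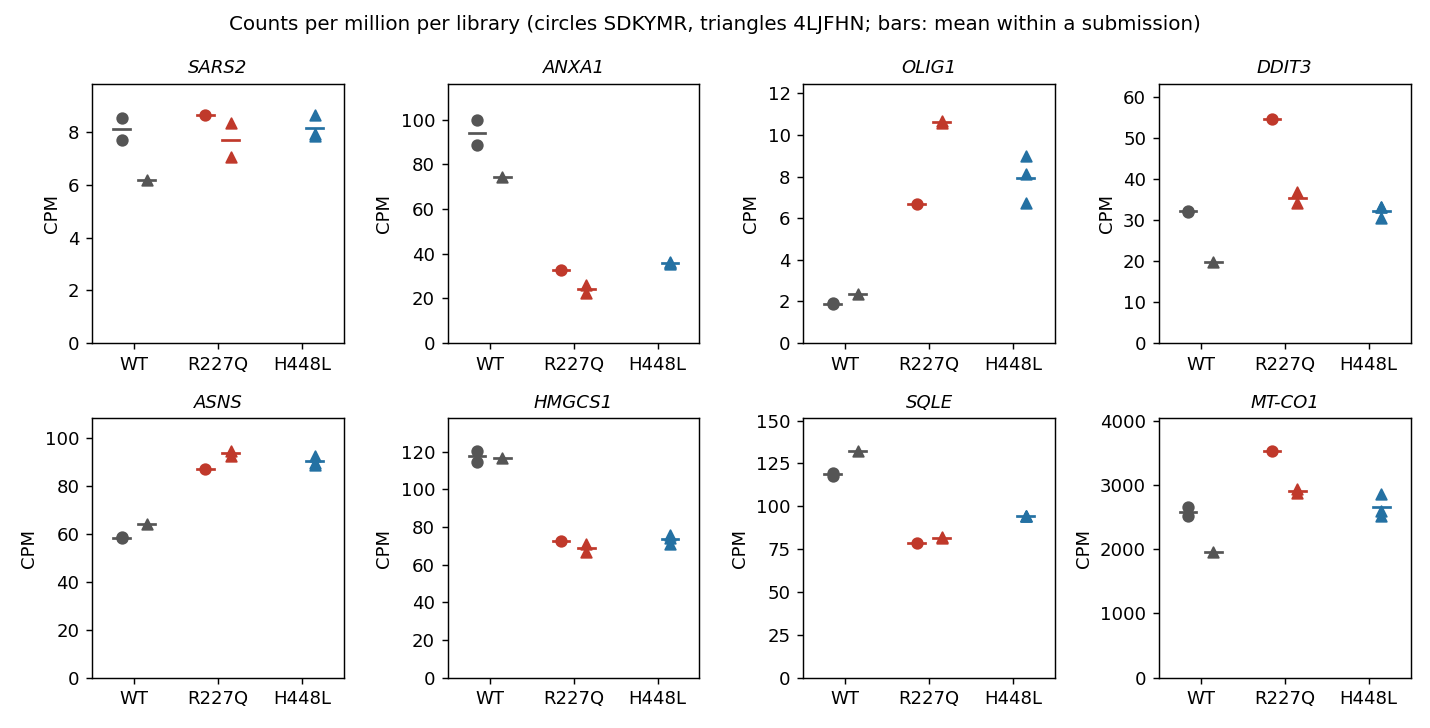
Level in CPM (vertical axis, from 0) in each library for 8 genes, by group; circles are SDKYMR libraries, triangles are 4LJFHN libraries and bars are means within a submission. ANXA1 lay between 74.3 and 99.9 CPM in the WT libraries and between 22.3 and 36.4 CPM in the variant libraries, while SARS2 overlapped between groups.

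The comparison of R227Q with WT asked how expression differs when the cells depend, by design, on R227Q SARS2. ANXA1, which encodes the phospholipid-binding protein annexin A1, was 2.99-fold lower in R227Q cells (log2 fold change −1.58 ± 0.06 (SE), 3 libraries per group). OLIG1, a transcription factor of the neural lineage, was 3.90-fold higher, and GDF15, a secreted cytokine induced by mitochondrial stress, was 2.90-fold higher. Genes of the integrated stress response, which is run by the transcription factor ATF4, rose as a group, and enzymes of cholesterol synthesis fell as a group. Transcripts for mitochondrial ribosomal proteins, the cell cycle and replication-dependent histones were also lower as groups at the preset correlation, calls that were lost otherwise (adjusted p = 0.160, 0.160 and 0.152 with an estimated correlation).

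Single genes moved in both directions. OLIG1 rose by a log2 fold change of 1.97 ± 0.17 (edgeR adjusted p = 1.9e-09), GDF15 by 1.53 ± 0.17 (1.5e-07) and CRABP1, a retinoic acid carrier, by 1.69 ± 0.12 (4.1e-11). INHBE, an inhibin beta subunit, rose by 1.47 ± 0.13 (edgeR adjusted p = 2.8e-09), NEUROG2, a neurogenic transcription factor, by 1.45 ± 0.13 (3.4e-09), and AKR1C1, an aldo-keto reductase, by 1.19 ± 0.12 (1.4e-08). ANXA1 (ENSG00000135046, chromosome 9, 73151757 to 73170393) went from 88.7, 99.9 and 74.3 CPM in WT 1 to 3 to 32.7, 26.1 and 22.3 CPM in R227Q 1 to 3 (edgeR adjusted p = 9.1e-17). LGSN, a lens protein of the glutamine synthetase family (−1.62 ± 0.16, edgeR adjusted p = 1.5e-08), PTN, a heparin-binding growth factor (−1.21 ± 0.09, 1.2e-10), and MME, a membrane endopeptidase (−1.05 ± 0.07, 2.5e-11), fell as well. The signs held within submissions: ANXA1 differed by −1.53 in SDKYMR and −1.62 in 4LJFHN, OLIG1 by 1.72 and 2.09, CRABP1 by 1.79 and 1.46, and GDF15 by 1.66 and 1.23.

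In the integrated stress response list, 16 of 29 tested members rose in R227Q cells and 13 did not pass, against 20 that rose when adjusted over the list alone. The median log2 fold change was 0.25 (camera adjusted p = 1.41e-08, and adjusted p = 0.0121 with an estimated correlation). DDIT3, the stress transcription factor CHOP, rose by 0.78 ± 0.06 (0.75 in SDKYMR and 0.83 in 4LJFHN), ASNS, asparagine synthetase, by 0.55 ± 0.05, and CHAC1, which degrades glutathione, by 0.88 ± 0.11 (edgeR adjusted p = 8.4e-10, 3.0e-09 and 5.1e-07). The DDIT3 value is uncertain because the gene overlaps MARS, MBD6 and AC022506.1. ATF4 itself stood at 0.13 ± 0.04 (edgeR adjusted p = 0.027), a call that was lost without WT 1 (0.10), WT 3 (0.14), R227Q 1 (0.12) or R227Q 2 (0.12). Without the submission term its value turned to −0.043. TRIB3, a pseudokinase induced by ATF4, stood at 0.23 (edgeR adjusted p = 0.022). Its call was lost without WT 2 (0.23), WT 3 (0.22), R227Q 1 (0.25) or R227Q 3 (0.20). The calls of DDIT3 (0.55), CHAC1 (0.54) and TRIB3 (0.03) were also lost without the submission term (edgeR adjusted p = 0.24, 0.43 and 0.95).

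Serine synthesis and mitochondrial one-carbon enzymes, the suppliers of serine and folate-bound carbon, had 8 of 14 tested members that rose, and 8 when adjusted over the list alone (median 0.15, camera adjusted p = 0.00498). That call was not kept with a correlation taken from the data (adjusted p = 0.176 with an estimated correlation). PCK2, mitochondrial phosphoenolpyruvate carboxykinase, rose by 0.72 ± 0.06, SHMT2, mitochondrial serine hydroxymethyltransferase, by 0.35 ± 0.04, and PHGDH, the first enzyme of serine synthesis, by 0.28 ± 0.04 (edgeR adjusted p = 7.0e-10, 1.5e-07 and 2.8e-05). The SHMT2 (0.27) and PHGDH (0.20) calls were lost without the submission term (edgeR adjusted p = 0.18 and 0.34). PSAT1 (0.05 ± 0.04) and MTHFD2 (−0.05 ± 0.04), enzymes of the same routes, did not pass (edgeR adjusted p = 0.52 and 0.40).

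Transcripts encoded in mitochondrial DNA were uneven. Of 13 tested, 7 rose and 2 fell, and 8 rose and 2 fell when adjusted over the list alone (median 0.12, camera adjusted p = 0.00941, adjusted p = 0.473 with an estimated correlation). MT-CO1, a cytochrome c oxidase subunit, rose by 0.50 ± 0.04 (0.44 in SDKYMR and 0.56 in 4LJFHN) and MT-ND4, a complex I subunit, by 0.40 ± 0.04 (edgeR adjusted p = 1.2e-09 and 5.1e-09), while MT-ATP8 and MT-ND3 fell by 0.22 and 0.21 on the log2 scale. The MT-ATP8 call was lost without R227Q 1 (−0.12) and its value was −0.33 without WT 3, and the MT-ND3 call without WT 1 (−0.19), WT 3 (−0.15), R227Q 1 (−0.27), R227Q 2 (−0.18) or R227Q 3 (−0.21). Cytosolic ribosomal protein genes had 22 of 52 members that rose and 2 that fell, RPL24 and RPL15, and 28 and 2 when adjusted over the list alone (median 0.09, camera adjusted p = 1.61e-04, adjusted p = 0.322 with an estimated correlation). RPL27 rose by 0.22 ± 0.04 and RPL24 fell by 0.21 on the log2 scale. Without the submission term the mitochondrial median was −0.01 and neither list passed the test (camera adjusted p = 0.83 and 0.071). Both families have near-identical copies elsewhere in the genome, so their counts are uncertain.

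Sterol biosynthesis genes moved most uniformly of the lists. In R227Q cells 20 of 23 tested members fell, 1 rose and 2 did not pass, with the same counts when adjusted over the list alone (median −0.37, camera adjusted p = 3.29e-14, adjusted p = 0.0121 with an estimated correlation). HMGCS1, which makes the HMG-CoA used for cholesterol (chromosome 5, 43289395 to 43313512), fell by 0.74 on the log2 scale (SE 0.05, edgeR adjusted p = 1.5e-11), with −0.70 in SDKYMR and −0.77 in 4LJFHN. SQLE, squalene epoxidase, fell by 0.66 (SE 0.05, 2.5e-11) and MSMO1, a sterol demethylase, by 0.56 (SE 0.05, 1.8e-09). HMGCS1 went from 120.2, 114.7 and 116.6 CPM in WT to 72.5, 71.0 and 66.6 CPM in R227Q. The member that rose was TM7SF2, a sterol reductase, at 0.18, whose call was lost without any 1 of the WT or R227Q libraries (WT 1 0.17, WT 2 0.19, WT 3 0.21, R227Q 1 0.15, R227Q 2 0.20 and R227Q 3 0.18). HMGCS1 overlaps an antisense gene by 1445 bases.

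Further lists were lower in R227Q cells. Mitochondrial ribosomal proteins had 17 of 54 members that fell and 37 that did not pass, and 20 that fell with 1 that rose when adjusted over the list alone (median −0.10, camera adjusted p = 2.51e-04, adjusted p = 0.160 with an estimated correlation). MRPL3 fell by 0.46 and MRPL20 by 0.33 on the log2 scale (SE 0.04 each). Among cell cycle and proliferation genes 13 of 26 fell, and 14 when adjusted over the list alone (median −0.11, camera adjusted p = 2.68e-04, adjusted p = 0.160 with an estimated correlation). CCNB1, a mitotic cyclin, fell by 0.30 and MCM5, a replication helicase subunit, by 0.32 on the log2 scale. ER chaperones, which fold secreted proteins, had 7 of 18 members that fell and 1 that rose, XBP1, a transcription factor that induces such chaperones, whose call was lost without R227Q 1 (0.19). When adjusted over the list alone these were 9 and 1 (median −0.10, camera adjusted p = 0.00315, adjusted p = 0.176 with an estimated correlation). MANF, a secreted ER protein, fell by 0.41 and DNAJB11, a chaperone, by 0.31 on the log2 scale. The list's call was lost without the submission term (camera adjusted p = 0.15) and after correction for GC content and length (0.052).

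Replication-dependent histones, whose mRNAs mostly lack poly-A tails, had 5 of 15 members that fell, and 6 when adjusted over the list alone (median −0.47, camera adjusted p = 0.00498, adjusted p = 0.152 with an estimated correlation). H4C3 fell by 0.65 on the log2 scale (SE 0.09), with −0.91 in SDKYMR and −0.39 in 4LJFHN, and −0.39 without R227Q 1. H1-4 stood at −1.03 ± 0.13 and H1-2 at −0.68 ± 0.09 (edgeR adjusted p = 1.5e-06 and 3.2e-06), and both calls were lost without WT 3 (−0.59 and −0.42). Histone genes share sequence, so reads could be divided among them.

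The lists in the rest of the R227Q comparison did not pass the list test. Mitochondrial biogenesis regulators had 1 member that rose and 3 that fell of 16 (camera adjusted p = 0.0678), and 1 and 4 when adjusted over the list alone. TFAM, which packages mitochondrial DNA, stood at −0.19 ± 0.05 (edgeR adjusted p = 0.016), a call lost without WT 3 (−0.26), R227Q 1 (−0.13) or R227Q 2 (−0.16). Mitochondrial chaperones and proteases had 3 of 15 that fell (0.119), or 4 when adjusted over the list alone, with GRPEL1, a cofactor of mitochondrial HSP70, at −0.25 ± 0.05. HSPD1, the mitochondrial chaperone HSP60, stood at −0.11 ± 0.03 (edgeR adjusted p = 0.027), a call lost without WT 1 (−0.11), WT 3 (−0.07), R227Q 1 (−0.15), R227Q 2 (−0.10) or R227Q 3 (−0.10). LONP1, a mitochondrial protease, at −0.03 ± 0.05 and MYC, a growth transcription factor outside these lists, at 0.24 ± 0.15 did not pass (edgeR adjusted p = 0.73 and 0.30). Interferon-stimulated genes had 2 of 16 that rose (0.0678), or 1 when adjusted over the list alone, with IFITM1, an antiviral membrane protein, at 1.03 ± 0.11 (edgeR adjusted p = 1.3e-07). That list passed without R227Q 3 (median 0.17, camera adjusted p = 0.042 at the preset correlation). With all libraries and an estimated correlation its camera adjusted p was 0.176. Glycolysis and hypoxia targets had 2 higher and 4 lower of 28 (0.272), or 2 and 8 when adjusted over the list alone. The tricarboxylic acid cycle and fatty acid oxidation list had 2 higher and 3 lower of 30 (0.346) by either adjustment, also when adjusted over the list alone, and its members PDHA1 and PDHB, subunits of pyruvate dehydrogenase, each fell by 0.31 on the log2 scale. Cytosolic aminoacyl-tRNA synthetases had 2 higher and 3 lower of 20 (0.649), the same when adjusted over the list alone.

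Nuclear OXPHOS subunits, the nuclear-encoded parts of the respiratory chain, had 4 higher and 7 lower of 57 (camera adjusted p = 0.999), the same when adjusted over the list alone, with a median of 0.00 and a mean of −0.00 of opposite signs. The mitochondrial aminoacyl-tRNA synthetases had 2 of 16 that rose (0.727), and 0 by edgeR when adjusted over the list alone, with 3 higher and 1 lower at an unadjusted p under 0.05. DESeq2 called 0 and limma-voom 2 over all genes, and the list's median (−0.06) and mean (0.01) had opposite signs. Markers of other cell types had few tested members and did not pass: epithelial cells 2 higher of 5 (0.169), fibroblasts 2 higher and 1 lower of 8 (0.678), haematopoietic cells 2 higher of 7 (0.544), and neuronal and embryonic kidney lines 1 higher and 2 lower of 8 (0.678). When adjusted over the list alone these were 2 higher, 2 higher and 1 lower, 3 higher and 1 lower, and 1 higher and 2 lower. The haematopoietic median was −0.08 with a mean of 0.11, and the neuronal and kidney test pointed down although its median (0.03) and mean (0.02) were positive.

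Over all genes, 2944 of 16908 passed the edgeR quasi-likelihood test for R227Q against WT at an adjusted p under 0.05, 1268 of them higher (43.1%) and 1676 lower. Changes were mostly small: the median absolute log2 fold change of these genes was 0.29, 129 rose and 34 fell by at least 2-fold, and 371 rose and 120 fell by at least 1.5-fold. Each of the 2944 had the same sign in both submissions, although the fit that chose them used both. The count was 1093 without WT 3, the sole WT library of 4LJFHN, 1278 without R227Q 1, 1138 within 4LJFHN alone, 1546 with DESeq2 and 312 without the submission term. With upper-quartile factors more genes were higher than lower (1565 and 1335), so the balance of directions depended on the scaling.

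The comparison of H448L with WT asked the corresponding question for H448L SARS2, whose libraries all came from submission 4LJFHN. The submission term was therefore estimated from WT and R227Q libraries, so R227Q libraries also entered the H448L fold changes. In fits without WT 3, H448L was compared with WT only through R227Q libraries. In H448L cells ANXA1 was 2.07-fold lower than in WT (log2 fold change −1.05 ± 0.07 (SE), 3 libraries per group) and OLIG1 was 2.93-fold higher. The integrated stress response list rose and the sterol biosynthesis list fell again, with GDF15 higher and HMGCS1 lower. TERT, the catalytic subunit of telomerase, and HPGD, which inactivates prostaglandins, were among the largest rises.

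OLIG1 rose by a log2 fold change of 1.55 ± 0.19 (edgeR adjusted p = 4.0e-06), CAMK2B, a calcium-dependent kinase, by 1.35 ± 0.19 (1.8e-05), NEUROG2 by 1.19 ± 0.16 (1.0e-05) and INHBE by 1.15 ± 0.15 (6.9e-06). TERT rose by 1.10 ± 0.20 (edgeR adjusted p = 5.3e-04), HPGD by 1.04 ± 0.12 (9.4e-07) and GDF15 rose 2.30-fold (2.6e-04). The TERT rise was not particular to H448L, since it was 1.09 ± 0.16 in R227Q against WT (edgeR adjusted p = 1.5e-05). TERT had only 56, 39 and 29 counts in WT 1 to 3, and its H448L call was lost without the submission term (0.72, edgeR adjusted p = 0.12). LGSN (−1.41 ± 0.19, edgeR adjusted p = 9.7e-06), ANXA1 (3.3e-10), PTN (−0.92 ± 0.10, 5.5e-07), MME (−0.86 ± 0.08, 5.3e-08) and MIR302CHG, the host transcript of a microRNA cluster of pluripotent cells (−0.87 ± 0.13, 4.4e-05), fell. Within 4LJFHN the differences were 1.65 for OLIG1, 0.94 for GDF15 and −1.07 for ANXA1, which stood at 35.3, 36.0 and 36.4 CPM in H448L 1 to 3 against 74.3 CPM in WT 3.

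In the integrated stress response list 7 of 29 members rose, 1 fell and 21 did not pass, against 12 and 1 when adjusted over the list alone (median 0.17, camera adjusted p = 3.08e-05, adjusted p = 0.0385 with an estimated correlation). DDIT3 rose by 0.65 ± 0.08 and ASNS by 0.48 ± 0.06 (edgeR adjusted p = 4.2e-06 and 1.6e-06). The DDIT3 call was lost without the submission term (0.14, edgeR adjusted p = 0.71). The DDIT3 level was 32.3, 31.9 and 19.7 CPM in WT 1 to 3 and between 30.4 and 33.2 CPM in the H448L libraries. WT 3, the lowest, is the sole WT library of 4LJFHN, which holds the H448L libraries. CHAC1 stood at 0.74 ± 0.14 (edgeR adjusted p = 8.7e-04), a call that was lost without WT 3 (0.64). Without the submission term its value turned to −0.040. The member that fell was KLHL24, a ubiquitin ligase adaptor, a call lost without WT 1 (−0.29), WT 2 (−0.28), WT 3 (−0.28), R227Q 1 (−0.29), R227Q 2 (−0.27), H448L 2 (−0.29) or H448L 3 (−0.21). ATF4 (0.13 ± 0.05, edgeR adjusted p = 0.11) did not pass. Serine synthesis and mitochondrial one-carbon enzymes had 4 of 14 that rose, and 5 higher with 1 lower when adjusted over the list alone, and the list did not pass (median 0.06, camera adjusted p = 0.159). PCK2 rose by 0.62 ± 0.07 (edgeR adjusted p = 9.4e-07). PHGDH stood at 0.23 ± 0.05 (0.0049), a call lost without WT 3 (0.28) or R227Q 1 (0.20). SHMT2 stood at 0.18 ± 0.05 (0.013), a call lost without WT 3 (0.19), R227Q 1 (0.17) or H448L 2 (0.17). Without the submission term the calls of PCK2 (0.45), PHGDH (0.050) and SHMT2 (0.0080) were lost (edgeR adjusted p = 0.073, 0.76 and 0.96).

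Sterol biosynthesis genes again moved nearly as one, with 17 of 23 members that fell, 1 that rose and 5 that did not pass, and 19 and 1 when adjusted over the list alone (median −0.34, camera adjusted p = 1.62e-13, adjusted p = 0.0160 with an estimated correlation). HMGCS1 fell by 0.66 on the log2 scale (SE 0.06), SQLE by 0.48 (SE 0.05) and FDFT1, squalene synthase, by 0.41 (SE 0.04), with edgeR adjusted p = 1.6e-08, 6.4e-07 and 5.5e-07. TM7SF2 was again the member that rose (0.24), and its call was kept only without H448L 2. It was lost without WT 1 (0.23), WT 2 (0.24), WT 3 (0.27), R227Q 1 (0.21), R227Q 2 (0.23), R227Q 3 (0.23), H448L 1 (0.24) or H448L 3 (0.17). ER chaperones had 6 of 18 that fell, and 10 lower with 1 higher when adjusted over the list alone (median −0.13, camera adjusted p = 4.37e-04, adjusted p = 0.168 with an estimated correlation), with MANF at −0.39 ± 0.05 and DNAJB11 at −0.30 ± 0.05. Without the submission term that list had a median of 0.03 and did not pass (camera adjusted p = 0.35).

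Mitochondrial ribosomal proteins had 5 of 54 members that fell and 1 that rose, MRPL10, and 9 and 1 when adjusted over the list alone (median −0.08, camera adjusted p = 0.00153, adjusted p = 0.186 with an estimated correlation). MRPL3 fell by 0.33 on the log2 scale (SE 0.05). The MRPL10 call was lost without WT 1 (0.27), WT 3 (0.12), R227Q 2 (0.26), H448L 1 (0.25) or H448L 3 (0.24), and its value turned to −0.18 without the submission term. Cell cycle genes had 8 of 26 that fell, and 9 lower with 1 higher when adjusted over the list alone (median −0.09, camera adjusted p = 4.26e-04, adjusted p = 0.168 with an estimated correlation), with CDC20, an activator of mitotic protein breakdown, at −0.31 ± 0.05. Cytosolic ribosomal proteins had 13 of 52 that rose and 3 that fell, and 19 and 3 when adjusted over the list alone (median 0.08, camera adjusted p = 2.02e-04, adjusted p = 0.492 with an estimated correlation), with RPS29 at 0.21 ± 0.04. That call was lost without the submission term (median 0.03, camera adjusted p = 0.29). Histones had 4 of 15 that fell, and 6 when adjusted over the list alone (median −0.22, camera adjusted p = 0.00712, adjusted p = 0.165 with an estimated correlation). H4C3 fell by 0.67 on the log2 scale (SE 0.10). For H4C3, H448L against WT, the value was −1.02 without WT 3, a comparison made only through R227Q libraries. The list's call was lost without WT 3 (median −0.24, camera adjusted p = 0.058).

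Mitochondrially encoded mRNAs had 3 of 13 that rose and 1 that fell, and 6 and 1 when adjusted over the list alone, and the list did not pass (median 0.11, camera adjusted p = 0.0549). MT-CO1 rose by 0.38 ± 0.05 and MT-ND4 by 0.35 ± 0.04 (edgeR adjusted p = 5.8e-06 and 2.5e-06). MT-ATP8, an ATP synthase subunit, stood at −0.26 ± 0.06 (0.0073), a call lost without R227Q 1 (−0.20), and at −0.41 without WT 3. The list passed without WT 1 (median 0.12), H448L 2 (0.13) or H448L 3 (0.13), with camera adjusted p = 0.025, 0.024 and 0.022 at the preset correlation. With all libraries and an estimated correlation its camera adjusted p was 0.621.

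The lists that follow did not pass for H448L. The counts of higher and lower members were 1 and 2 of 28 glycolysis and hypoxia targets and 1 and 4 of 30 tricarboxylic acid cycle and fatty acid oxidation genes (camera adjusted p = 0.353 each), equal to the counts adjusted over the list alone. Mitochondrial chaperones and proteases had 2 of 15 that fell (0.353), or 3 when adjusted over the list alone, and interferon-stimulated genes 1 of 16 that rose (0.485), or 1 higher and 1 lower when adjusted over the list alone, with IFITM1 at 0.91 ± 0.15 (edgeR adjusted p = 1.2e-04). Cytosolic aminoacyl-tRNA synthetases had 1 higher of 20 (0.742) and mitochondrial ones 1 lower of 16 (0.742), LARS2, the leucine enzyme, at −0.26, both the same when adjusted over the list alone. The LARS2 call was lost without WT 3 (−0.36), R227Q 1 or H448L 2 (−0.21), and the test of its list pointed down against a median of 0.03. Haematopoietic markers had 1 higher of 7 (0.232), fibroblast markers 1 lower of 8 (0.742) and neuronal and kidney markers 1 lower of 8 (0.742), the same when adjusted over the list alone. The last had a median of 0.08 and a test pointing down. HSPD1 (−0.09 ± 0.04), LONP1 (−0.05 ± 0.05), TFAM (−0.17 ± 0.06) and MYC (0.31 ± 0.20) did not pass for H448L (edgeR adjusted p = 0.21, 0.66, 0.10 and 0.40).

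Nuclear OXPHOS subunits had 1 member of 57 lower in H448L cells (camera adjusted p = 0.428), and 0 when adjusted over the list alone, where 10 higher and 4 lower had an unadjusted edgeR p under 0.05, DESeq2 called 1 and limma-voom 1 in each direction over all genes. Mitochondrial biogenesis regulators had 0 of 16 called by edgeR over all genes or when adjusted over the list alone (0.791), with 2 higher and 2 lower at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom, and a median of −0.00 against a mean of 0.00. Epithelial markers had 0 of 5 called by edgeR over all genes or when adjusted over the list alone (0.485), with 1 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom.

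Over all genes, 1347 of 16908 passed the edgeR quasi-likelihood test for H448L against WT, 503 higher (37.3%) and 844 lower, with a median absolute log2 fold change of 0.31. The balance depended on the settings, with 143 higher and 590 lower by DESeq2, 584 and 652 with upper-quartile factors, and 76 and 71 without the submission term. By at least 2-fold, 69 rose and 14 fell. The count was 253 without WT 3, 771 without R227Q 1, 734 within 4LJFHN alone, 733 with DESeq2, 756 with the R227Q libraries left out and 147 without the submission term.

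The direct comparison of H448L with R227Q asked whether the variants differ from each other. CRABP1, the retinoic acid carrier, was lower in H448L than in R227Q (log2 fold change −0.90 ± 0.12 (SE), edgeR adjusted p = 8.1e-05, 3 libraries per group). ANXA1 was higher (0.53 ± 0.08, 3.9e-04), as was RPL22L1, a paralog of a ribosomal protein (0.41 ± 0.05, 5.4e-05). The CRABP1 level was 18.0 and 15.8 CPM in R227Q 2 and 3 and 9.71, 7.94 and 10.4 CPM in H448L 1 to 3, within submission 4LJFHN.

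Of 16908 genes 35 passed, 14 higher and 21 lower in H448L than in R227Q, with a median absolute log2 fold change of 0.26, and 1838 had an unadjusted p under 0.05. EIF3A, a translation initiation factor subunit, was higher (0.33 ± 0.06, edgeR adjusted p = 0.0047), and TSC22D3, a glucocorticoid-induced regulator (−0.33 ± 0.05, 0.0022), and MT1F, a metal-binding metallothionein (−0.29 ± 0.05, 0.0021), were lower. Those 3 calls were lost without R227Q 3 (0.27, −0.28 and −0.28). A long non-coding RNA gene without a symbol in the tables (ENSG00000253321, chromosome 5, 90353037 to 90356609), named here after its values were seen, was higher by 4.14 ± 0.44 (edgeR adjusted p = 5.1e-06) at low levels: 9, 7 and 9 counts in WT 1 to 3, 2, 2 and 1 in R227Q 1 to 3, and 21, 35 and 34 in H448L 1 to 3.

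Between the variants, DDIT3 (−0.14, edgeR adjusted p = 0.46), ASNS (−0.07, 0.66), GDF15 (−0.33 ± 0.15, 0.40), SHMT2 (−0.17 ± 0.04, 0.061) and DDIT4, a stress-induced inhibitor of mTORC1 (−0.23 ± 0.06, 0.085), did not pass the edgeR test with the main settings. SHMT2 passed with DESeq2 (adjusted p = 0.010) and, by edgeR, with every gene that had a count (0.0090), protein-coding genes alone (0.024), without H448L 1 (0.034) and with the genes that had GC content and length, uncorrected (0.048). DDIT4 passed with every gene that had a count (0.024) and protein-coding genes alone (0.037). As a list the integrated stress response was lower in H448L than in R227Q (median −0.11, camera adjusted p = 2.72e-04, adjusted p = 0.104 with an estimated correlation). Of its 29 members edgeR called 0 over all genes, 2 lower when adjusted over the list alone and 9 lower at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Sterol biosynthesis was higher (median 0.05, camera adjusted p = 0.0210, adjusted p = 0.238 with an estimated correlation), with 0 of 23 members called by edgeR, DESeq2 or limma-voom, 2 higher when adjusted over the list alone and 6 higher at an unadjusted p under 0.05. That call was lost without R227Q 2 (median 0.08), H448L 1 (0.06) or H448L 3 (0.04).

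Serine and one-carbon enzymes were lower (median −0.07, camera adjusted p = 0.0241, adjusted p = 0.330 with an estimated correlation), with 0 of 14 members called by edgeR and limma-voom, 1 by DESeq2, 1 lower when adjusted over the list alone and 3 lower at an unadjusted p under 0.05. The call was lost without WT 3 (median −0.07), R227Q 1 (−0.07), R227Q 3 (−0.06) or H448L 2 (−0.06). Mitochondrial biogenesis regulators were higher (median 0.06, camera adjusted p = 0.0267, adjusted p = 0.238 with an estimated correlation), with 0 of 16 members called by edgeR, DESeq2 or limma-voom, 0 when adjusted over the list alone and 2 higher at an unadjusted p under 0.05. It was lost without WT 1 (0.06), WT 3 (0.06), R227Q 1 (0.06), R227Q 2 (0.11), R227Q 3 (0.07), H448L 1 (0.08) or H448L 2 (0.06). The other lists reported here did not pass (camera adjusted p from 0.151 for interferon-stimulated genes to 0.910). Among them the mitochondrially encoded mRNAs were lower without H448L 1 (median −0.09, camera adjusted p = 0.012 at the preset correlation). With all libraries and an estimated correlation their camera adjusted p was 0.843. When adjusted over the list alone, the members passing in these other lists were 4 higher cell cycle genes, 2 lower mitochondrially encoded mRNAs, 1 lower cytosolic ribosomal protein and 1 fibroblast marker in each direction.

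The count of 35 rested on single libraries: it was 14 without WT 1, 21 without WT 3, 22 without R227Q 1, 4 without R227Q 3, 91 without H448L 1, 11 without H448L 2 and 12 without H448L 3. It was 54 with DESeq2, and only 12 of those were among the 35. The count was 122 with every gene that had a count and 76 with protein-coding genes alone. It was 22 with the WT libraries left out and 1 without the submission term.

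**Figure D2:**
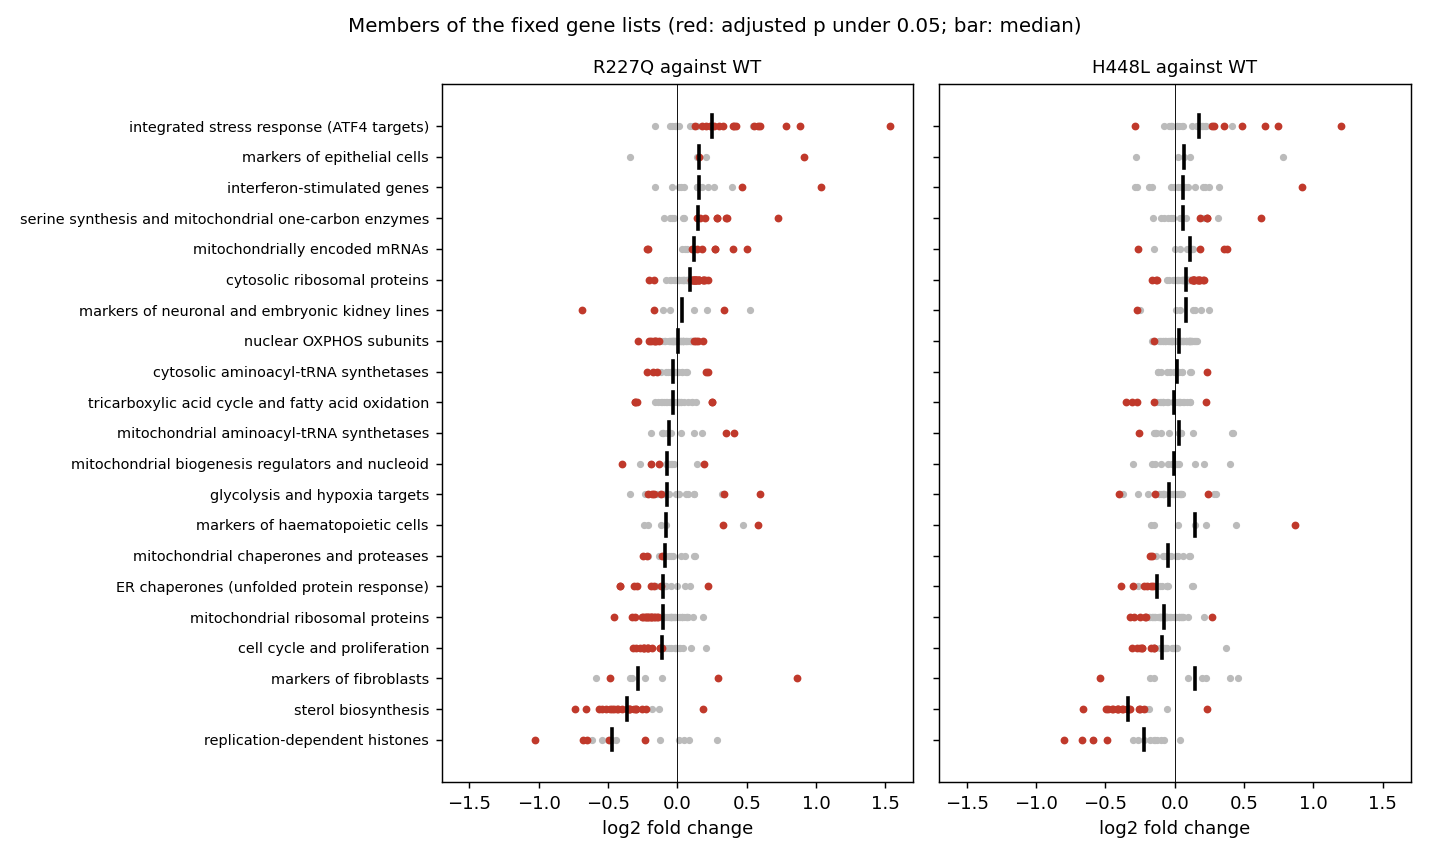
Log2 fold changes against WT (horizontal axis) of the tested members of the lists reported here, for R227Q and H448L; bars are medians, red marks members with an edgeR adjusted p under 0.05, and lists are ordered by the R227Q median. The integrated stress response had medians of 0.25 and 0.17 and sterol biosynthesis medians of −0.37 and −0.34.

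Both variants were then set side by side. Of the genes that passed against WT, 1120 did so in both variants, 402 higher in both, 717 lower in both and 1 in opposite directions, where 37.7 and 83.7 would be shared by independent lists of these sizes. Because both variants were compared with the same WT libraries, independent lists are not the value for no change. R227Q libraries also entered the H448L fold changes through the submission term. Simulated unchanged groups against shared controls gave a mean of 0.04 genes in both. No gene was changed in those simulations, so few calls could arise at all (means of 0.24 for R227Q and 0.14 for H448L). They therefore do not show how much the shared WT and R227Q libraries add to the 1120. HMGCS1, SQLE, ASNS, DDIT3, OLIG1 and ANXA1 were among the shared genes. Of the genes that passed for H448L, 83.1% also passed for R227Q, and 1824 passed for R227Q alone. Of the 1120, 10 differed between H448L and R227Q in the direct test, ANXA1 among them. The absolute change was larger in R227Q for 605 of the 1120 (54.0%), with medians of 0.33 and 0.31.

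Across genes, which are not independent replicates, the log2 fold changes of R227Q and H448L against WT had a Pearson r of 0.729 and a Spearman rho of 0.738, and 79.1% of genes had the same sign. Both comparisons used the same WT libraries, and 50 simulations of unchanged groups against shared controls gave a mean r of 0.551, a mean rho of 0.523 and 69.5% of the same sign. The covariance was 0.0649 against a simulated mean of 0.0233 (SD 5.96e-04), a difference of 0.0417. The 3 WT libraries could not be divided into parts of at least 2, so part of the excess may come from the shared controls. The R227Q libraries that entered the H448L fold changes through the submission term may add to it as well. With R227Q against WT taken within SDKYMR and H448L against WT within 4LJFHN, which share no library, r was 0.398, rho 0.427 and the covariance 0.0368, and 67.8% of genes had the same sign. For R227Q alone the differences in the 2 submissions had an r of 0.456, and 0 genes passed an edgeR test of a difference between the submissions' R227Q effects, with 736 at an unadjusted p under 0.05.

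**Figure D3:**
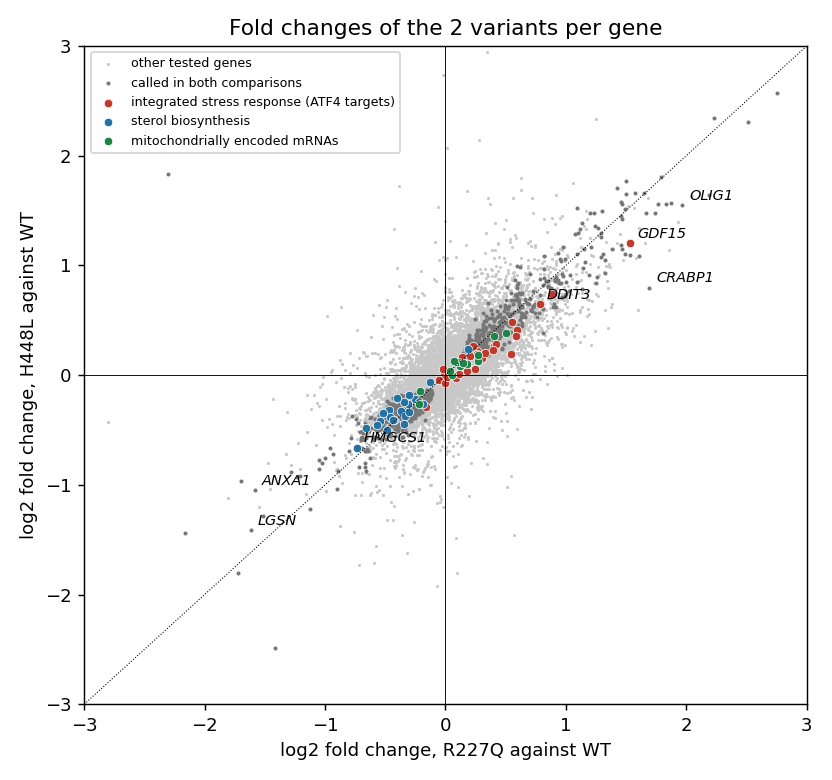
Log2 fold change of H448L against WT (vertical axis) over that of R227Q against WT (horizontal axis) for the 16908 tested genes, 5 of which lie outside the axes; dark grey marks genes called in both, red the integrated stress response, blue sterol biosynthesis and green mitochondrially encoded mRNAs, and the dotted line marks equal values. The sterol genes lie low in both variants, with medians of −0.37 and −0.34, except TM7SF2 (0.18 and 0.24).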

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

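The tests below were chosen after the main results were seen. The bounds for GC content and length behind the sterol genes, for the third pattern and for the splits were set before the results of those tests were seen, and the other bounds after.

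ERCC spike-in sequences are synthetic control RNAs that the labels do not mention. Their counts, summed over all of them, were above 3, the bound used for flagging, in 7 libraries. The sums were 11 in WT 1, 9 in WT 2, 4 in WT 3, 18 in R227Q 1, 5 in R227Q 2, 5 in H448L 2 and 7 in H448L 3. R227Q 3 had 2 and H448L 1 had 1. They made up 8.9e-06% to 1.47e-04% of the counts.

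The first pattern is that R227Q and H448L differed from WT at many genes in the same direction. Chance values of the shared WT libraries alone are argued against, since the covariance without a shared library was 0.0368, above the highest of 50 simulated values (0.00107). Simulated genes and libraries varied independently, so the real range for unchanged groups may be wider. Chance values common to all WT libraries, as from a shared culture, are not covered by that comparison. GC content and length alone are argued against as well, since r was 0.729 after correction and 0.733 for the same genes without it. The labels do not say how many lines or clones stand behind a genotype, so a property of the WT cells cannot be told apart from an effect of the variants, and the 35 genes that differed between H448L and R227Q could likewise be differences between clones. An effect of the variant SARS2 proteins may therefore be considered only as a hypothesis.

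The second pattern is that sterol biosynthesis genes were lower in both variants. After the GC and length correction the median nearer to 0 was −0.36, so that trend is not the whole cause. Leaving mitochondrial and ribosomal protein transcripts out of the library sizes moved the median by at most 0.00364. A property of the WT cells stays open here too, and an effect of the variants on the pathway was not tested apart from it.

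The third pattern is that more genes passed for R227Q (2944) than for H448L (1347). Fewer WT libraries in the H448L submission are argued against as the whole cause, since with 2 libraries of each variant against WT 3 the R227Q count was at least 1.64 times the H448L count, for each choice of H448L libraries (1123 and 684, 976 and 350, 1589 and 791). In these fits the spread came from the variant libraries, and WT 3 was assumed to vary like them. Larger changes in R227Q are a candidate explanation, since the covariance of its libraries' changes was 0.0925, above 0.0763, 0.0716 and 0.0786 for the H448L pairs. Those pairs share WT 3, and the covariance of each also holds its chance value. The median absolute log2 fold change of called genes was not larger in R227Q (0.29 against 0.31). Of the 1120 genes called in both, 54.0% changed more in R227Q. The median standard error of tested genes was 0.0977 for R227Q and 0.116 for H448L, and its part in the counts was not tested.

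Other splits of the same libraries into groups of 3 were too few for a share under 0.05. For R227Q against WT, 1 of 9 splits gave 2944 genes or more (the real one) and the highest other gave 0; a 10th, which follows the submission, could not be fitted. For H448L against WT it was 1 of 10, with 1347 genes and 0 for the highest other, and for H448L against R227Q 1 of 10, with 35 genes and 2 for the highest other.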

How the results depend on the processing

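The GC and length correction, its uncorrected counterpart and the unshared WT libraries were chosen after the results were seen. Depth limited genes near 1 CPM, where 1 count stood for 0.0770 to 0.101 CPM, and edgeR recovered 35.8% to 52.2% of genes at the smallest simulated fold and 59.7% to 73.1% of those changed by 1.5-fold from simulated counts. Over 25 alternatives, the values of 170 gene results kept their side of the threshold and any called direction 3692 times (17 values that did not pass changed sign), lost the call 481 times, gained one 16 times and reversed 15 times; 66 list results kept theirs 1589 times, lost 46 and gained 15. Of the 170 gene results, 129 could be scored with DESeq2 and 165 with protein-coding genes alone, and the rest were left out of these tallies. Counts with RLE or upper-quartile factors, limma-voom, a mean of at least 10 counts, thinning, or library sizes without mitochondrial and ribosomal protein genes stayed within 1.5 times. The causes of the changes below were not tested, except where fewer libraries or genes entered.

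In the order R227Q against WT, H448L against WT and H448L against R227Q, the counts were 2944, 1347 and 35. DESeq2 gave 1546, 733 and 54, of which 1543, 717 and 12 were among the main calls. No submission term gave 312, 147 and 1, with 12 lists in place of 20. Submission 4LJFHN alone gave 1138 and 734 with r = 0.817. The compared groups alone gave 756 for H448L against WT and 22 between the variants. Between the variants, every gene with a count gave 122 (r = 0.529) and protein-coding genes alone 76. Camera with an estimated correlation called 4 lists, and r was 0.398 with unshared WT libraries. Leaving out each library in turn gave 1093 to 3262, 253 to 1378 and 4 to 91 genes, 17 to 20 lists, and r from 0.635 to 0.819. The 253 and the 0.819 came without WT 3, where H448L was compared with WT only through R227Q libraries.

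Labels number the libraries 1 to 3 in each group. Deviations from group means correlated between same-numbered libraries of WT and R227Q at 0.66, −0.56 and 0.66, which follows the submissions. Same-numbered pairs with H448L lay between −0.04 and 0.07. No pairing by number was seen, but the submission difference within WT and R227Q could hide one. A replicate block without the submission term gave 151, 57 and 0 genes (edgeR) and 12 lists, and a block with it 2669, 1055 and 31 genes and 19 lists. In the block without the submission term, values reversed for R227Q at ATF4 (−0.046) and RPS3 (−0.022), and for H448L at HSP90B1 (0.078), RPL27 (−0.018), RPS18 (−0.14), MRPL10 (−0.16) and PYCR1 (−0.051).

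With no block and no submission term they reversed for R227Q at ATF4 (−0.043) and RPS3 (−0.011), and for H448L at CHAC1 (−0.040), HSP90B1 (0.064), RPL27 (−0.024), RPS18 (−0.16), MRPL10 (−0.18) and PYCR1 (−0.062).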

Other observations

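The genes in this part were chosen after their values were seen, and no cause was tested for them. ASS1, argininosuccinate synthetase of arginine synthesis, rose in both variants against WT, by 1.00 ± 0.05 (SE) in R227Q and 0.74 ± 0.06 in H448L on the log2 scale (edgeR adjusted p = 7.5e-14 and 1.3e-08). TFRC, the transferrin receptor for iron uptake, fell in both (−0.69 ± 0.05 and −0.51 ± 0.05, edgeR adjusted p = 2.0e-11 and 5.5e-07). Actin-related TMSB4X, which binds actin monomers, fell by like amounts (−0.56 ± 0.05 and −0.57 ± 0.06, 1.1e-08 and 5.5e-07).

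MT1F and MT1M encode metallothioneins, small metal-binding proteins with near-identical members whose reads are uncertain. Both rose in R227Q against WT (0.29 and 0.38, edgeR adjusted p = 3.7e-05 and 3.2e-07), whereas in H448L they stood at −0.00 and 0.11 and did not pass. In the direct test of H448L against R227Q, MT1F and MT1M were lower (−0.29 and −0.27, edgeR adjusted p = 0.0021 and 0.0022), calls lost without R227Q 3 (−0.28 and −0.25). Of their relatives, MT1X (−0.16), MT1E (−0.12) and MT1G (−0.09) did not pass that test (edgeR adjusted p = 0.073, 0.16 and 0.97). MT2A passed it (−0.16, edgeR adjusted p = 0.040), a call lost without any 1 library (−0.19 to −0.15) except H448L 1. Metallothioneins were not tested as a group.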
